A study of Mus musculus with 79 samples.

How the data were processed

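Total RNA from the left hippocampus and the frontal cortex of female mice was measured on Illumina MouseRef-8 v2 bead arrays. The signal file holds intensity values that, per the file headers, give 1 signal column per array with a detection p-value beside it. The deposited intensities were background-subtracted within each array, since 21.8% to 26.3% of the values of a hippocampal array and 23.0% to 25.7% of those of a cortical array lay below 0, and were not normalized between arrays. The deposited detection p-values compare each probe with the negative control beads of its array. A further table by the authors holds log2 values of 18960 of the 25697 probes, quantile normalized within each tissue. The submitters' processing notes name BeadStudio, GenomeStudio and Partek without versions.

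The analysis started from the signal table in R 4.3.3 with limma 3.58.1, and files were read with the data.table package (version 1.17.8). The neqc function corrected the background with the detection p-values, added an offset of 16 and quantile normalized all 79 arrays together on the log2 scale. A probe entered the comparisons of a tissue when its detection p was under 0.05 on at least 8 arrays of that tissue, which left 14923 probes for the hippocampus and 14581 for the cortex. Gene symbols came from the platform annotation. It gave 1 symbol each to 17800 of the probes in the authors' table, and 17791 of their gene IDs were found in the reference gene table (assembly GRCm38.p6), where 0 symbols had changed. The 6737 probes outside the authors' table had no symbol here. Itgax had 0 named probes, and Cd33 had 1 probe.

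Groups, tissue, slide, animal, surgery session and day of collection came from the labels, and 0 sample columns were left unused. Within each tissue 1 linear model with the 4 groups was fitted (lmFit, then eBayes with an intensity trend). The 4 comparisons were APP/PS1 PBS against WT PBS (genotype), CD33 ASO against control ASO, control ASO against PBS and CD33 ASO against PBS, the last 3 all within APP/PS1. Genotype and both comparisons with PBS share the APP/PS1 PBS arrays, and the comparisons of oligonucleotides share treated arrays, so no overlap between their gene sets was tested. Probes with a Benjamini-Hochberg adjusted p under 0.05 were called. Values are log2 differences from limma, with the SE for the genes that open each comparison. A second fit had slide as a block, and its values are given for the lists and for a part of the genes. A difference between tissues was tested with duplicateCorrelation with animal as the block (consensus correlation 0.0801) over 15290 probes. Cd33 was also tested by a two-sided permutation test of the difference of means in Python 3.11.15 with scipy 1.17.1. The test was exact where a group had fewer than 10 arrays, and used 100000 resamples for the cortical comparison of both oligonucleotides. Figures were drawn with matplotlib 3.10.9.

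Before the data were examined, 29 gene lists, the comparisons, the alternatives and a rule for named genes were fixed. The rule took Cd33, App and Thy1 in every comparison, with a further gene that is not reported here, then the 10 largest rises and 10 largest falls among called genes (1 probe per gene, the one with the highest mean). It added up to 4 called members of each list with the largest change, or, where none was called, the 2 members with the highest mean as values. Trem2, Tyrobp, Cst7, Clec7a, Itgax, Apoe, Gfap, P2ry12, Tmem119 and Ttr were added as values wherever measured. Some of these genes are left out of the text for length. The 26 lists with at least 5 measured genes were tested with camera (preset correlation 0.01, adjusted over the lists), and beside it with camera's estimated correlation and with fry. A list "adjusted over the list alone" has its members' p-values adjusted within the list. Where a gene was detected on 0 arrays of the dimmer group, the difference is also given as a bound, with each value of that group raised to at least the lowest value of a detected probe on its array.

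The steps were tested on simulated data in which 200 probes were given known changes. A change of 1 on the log2 scale was found for 98.5% of the changed probes in the hippocampal comparison of both oligonucleotides and for 97% in the cortical one, and a change of 0.25 for 23.9% and 28.4%. False calls made up between 2.94% (cortical control ASO against PBS) and 10.3% (cortical genotype) of the calls in the comparisons within a tissue. Of 8 lists shifted by 0.3, 7 were called, as were 2 of 200 others. The simulated probes varied independently of each other and without slide effects, unlike those of the arrays. The rate of other lists called therefore does not carry over to the arrays. The precision of each value is limited by the number of arrays. Alternatives covered background correction, scaling, filtering, blocking by slide, session or replicate number, array weights, the authors' table, leaving out each array in turn and leaving out animals collected on another day. Without background correction, non-positive signals were set to the lowest positive signal before log2 and no offset was added. Differences near background are wider on that scale. Leaving out animals with Thy1 at or below the highest wild-type value and a choroid plexus covariate were added after the data had been seen. The sequences of the oligonucleotides, plaque load and protein levels were not used here.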

Results

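The study measured mRNA in the brain of female APP/PS1 mice, a transgenic line that forms amyloid plaques, and of wild-type littermates. CD33 is a sialic acid-binding receptor of microglia and other myeloid cells. An antisense oligonucleotide (ASO) against Cd33, a non-targeting control ASO or phosphate-buffered saline (PBS) was infused into the ventricle of APP/PS1 mice by an osmotic pump, at 75 µg per day and 6 µL per day for 14 days from 18 weeks of age. Wild-type (WT) mice received PBS. Tissue was collected at about 20.5 weeks of age, usually 17 days after surgery, and 4 animals were collected on another day. Those were CD33 ASO animals after 13, 13 and 16 days and an APP/PS1 PBS animal after 14 days. Collection after 13 days came before the stated 14 days of infusion had passed. The hippocampus gave 9 arrays with CD33 ASO, 11 with control ASO, 8 with PBS and 11 from WT mice. The cortex gave 10, 11, 8 and 11 arrays. The 79 arrays came from 40 animals, of which 39 gave both tissues. Between 13139 and 14446 of the 25697 probes were detected on a hippocampal array and between 13105 and 13766 on a cortical array. The median signal of an array ranged from 14.7 to 27.9 intensity units in the hippocampus and from 12.2 to 30.2 in the cortex. Each tissue was run on its own 5 slides, over which the groups were unevenly spread, and 4145 of 14923 hippocampal and 3200 of 14581 cortical probes differed between slides within groups. No probe (0 in both tissues) differed between the 3 surgery sessions.

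Thy1, a surface protein of neurons whose promoter cassette drives the transgenes in this line, separated the genotypes in the PBS groups. Its probe (gene ID 21838, chromosome 9, 44043384 to 44048579 in GRCm38.p6) gave 14.66 ± 0.090 (log2 signal, SD, n = 8) in the hippocampus of APP/PS1 mice and 13.89 ± 0.0799 (n = 11) in WT mice. The cortex gave 14.70 ± 0.0887 (n = 8) and 13.99 ± 0.0803 (n = 11). The difference was 0.77 (SE 0.0933, adjusted p = 3.2e-07) in the hippocampus and 0.71 (SE 0.101, adjusted p = 1.51e-06) in the cortex. Thy1 lay among the highest values of the arrays, where quantile normalization leaves few ranks above it, which limits how large a difference it can show. The probe for App, the mouse counterpart of one transgene, gave differences of 0.0541 (SE 0.0576, adjusted p = 0.873) and -0.11 (SE 0.0601, adjusted p = 0.408). Thy1 lay at or below the highest WT value of the tissue (14.03 in the hippocampus and 14.14 in the cortex) on 7 arrays from 4 animals labelled APP/PS1, of which 3 gave both tissues. On these arrays it was between 13.81 and 14.01. Of these arrays 2 hippocampal and 2 cortical ones were labelled control ASO, and 1 hippocampal and 2 cortical ones CD33 ASO. All other arrays labelled APP/PS1 lay at or above 14.51 in the hippocampus and 14.54 in the cortex. Cst7, a cystatin induced in microglia around plaques, had its lowest values of each group on these 7 arrays. The counts of called probes within a tissue, and a part of the lists and genes, are also given without these 4 animals, a choice made after the data had been seen. Those of the 4 with CD33 ASO were also collected on another day, after 16 and 13 days. Leaving them out therefore removes both features at once.

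**Figure D1:**
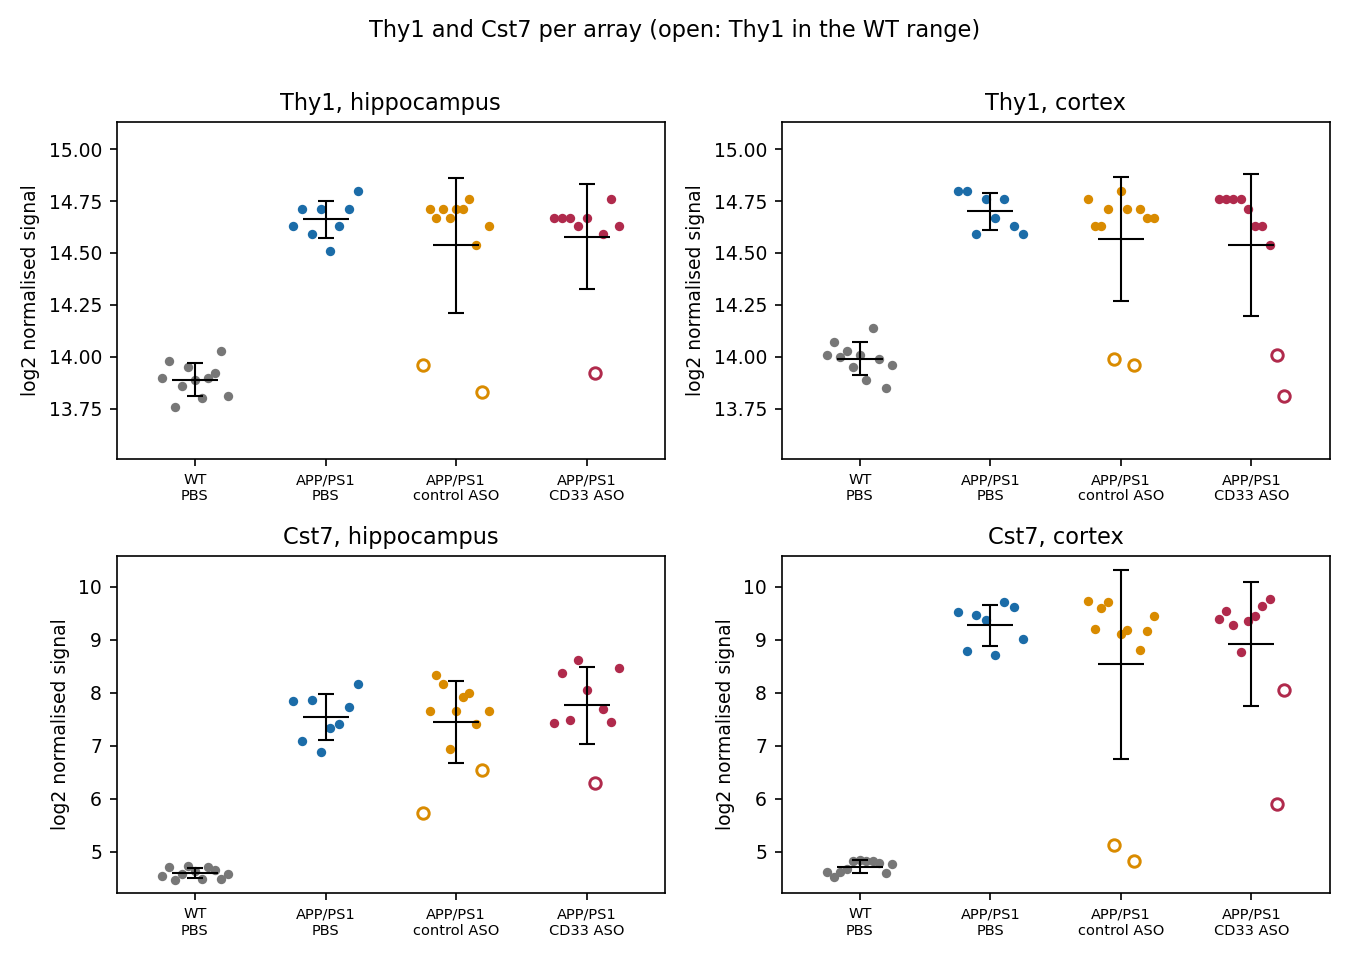
Thy1 and Cst7 as log2 signal (vertical axis) in each group (horizontal axis), with 1 panel per gene and tissue, 1 point per array and bars for the mean ± SD. Open circles mark the 7 arrays of animals labelled APP/PS1 whose Thy1, 13.81 to 14.01, lay at or below the highest WT value of the tissue.

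Cd33, the gene targeted by the CD33 ASO, was lower after that oligonucleotide in both tissues. In the hippocampus its probe (gene ID 12489, chromosome 7, 43527399 to 43537424) gave 4.78 ± 0.243 (log2 signal, SD, n = 9) with CD33 ASO, 6.49 ± 0.274 (n = 11) with control ASO, 6.20 ± 0.270 (n = 8) with PBS and 5.80 ± 0.136 (n = 11) in WT mice. In the cortex Cd33 gave 5.59 ± 0.533 (n = 10), 6.86 ± 0.217 (n = 11), 6.67 ± 0.236 (n = 8) and 5.83 ± 0.235 (n = 11). Against control ASO, Cd33 fell by 1.71 (SE 0.106, adjusted p = 1.08e-15) in the hippocampus and by 1.27 (SE 0.139, adjusted p = 7.24e-08) in the cortex. Against PBS it fell by 1.42 (SE 0.115, adjusted p = 8.21e-12) and by 1.08 (SE 0.151, adjusted p = 1.45e-05). The Cd33 probe was detected on 2 of 9 hippocampal and 8 of 10 cortical arrays with CD33 ASO, so the hippocampal level lay close to the background. The cortical arrays that did not detect it, replicates 9 (4.49) and 10 (5.04), were those of the animals with low Thy1. Without replicate 9 alone the cortical difference from control ASO was -1.15. In the setting without background correction, non-positive signals took the lowest positive signal and no offset was added, so differences near background widened. The difference in Cd33 against control ASO was then -5.62 in the hippocampus (adjusted p = 0.0129) and -3.64 in the cortex, where it no longer passed (adjusted p = 0.385). That against PBS was -5.26 (adjusted p = 0.0249) and -3.42 (adjusted p = 0.324). These values are not on the scale of the main fit.

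Genotype raised Cd33 in the cortex by 0.84 (SE 0.148, adjusted p = 7.15e-05), and by 1.08 without background correction, where it did not pass (adjusted p = 0.803). The hippocampal difference in Cd33 between genotypes, 0.40 (SE 0.11, adjusted p = 0.0702), did not pass, but did with slide as a block (0.44, adjusted p = 0.0387) and without PBS replicate 4 (0.48, adjusted p = 0.00797). Control ASO against PBS gave differences in Cd33 of 0.29 (SE 0.11, adjusted p = 0.0798, but 0.0392 without PBS replicate 1 and 0.0456 without control ASO replicate 6) in the hippocampus and 0.19 (SE 0.148, adjusted p = 0.758) in the cortex. In the two-sided permutation tests, adjusted over the 8 Cd33 comparisons, CD33 ASO against control ASO gave p = 1.19e-05 (exact, adjusted 7.07e-05) in the hippocampus and p = 2e-05 (100000 resamples, adjusted 7.07e-05) in the cortex, each the smallest that its test can give. Against PBS the exact permutation p was 8.23e-05 (adjusted 0.000146) in the hippocampus, the smallest possible, and 9.14e-05 (adjusted 0.000146) in the cortex. The exact permutation p for genotype was 0.00132 (adjusted 0.00176) and 2.65e-05 (adjusted 7.07e-05), the last being the smallest possible, and that for control ASO against PBS 0.0249 (adjusted 0.0285) and 0.0885 (adjusted 0.0885). Within slides that held both groups, Cd33 differed between CD33 ASO and control ASO by -2.04 to -1.46 on 3 hippocampal slides and by -1.56 to -0.93 on 4 cortical slides. Against PBS the range was -1.71 to -1.36 on 4 hippocampal and -1.29 to -0.73 on 4 cortical slides. For genotype it was 0.39 to 0.64 (3 of 3 slides higher) and 0.44 to 1.08 (5 of 5), and for control ASO against PBS -0.0842 to 0.098 (1 of 2) and -0.0275 to 0.47 (4 of 5).

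**Figure D2:**
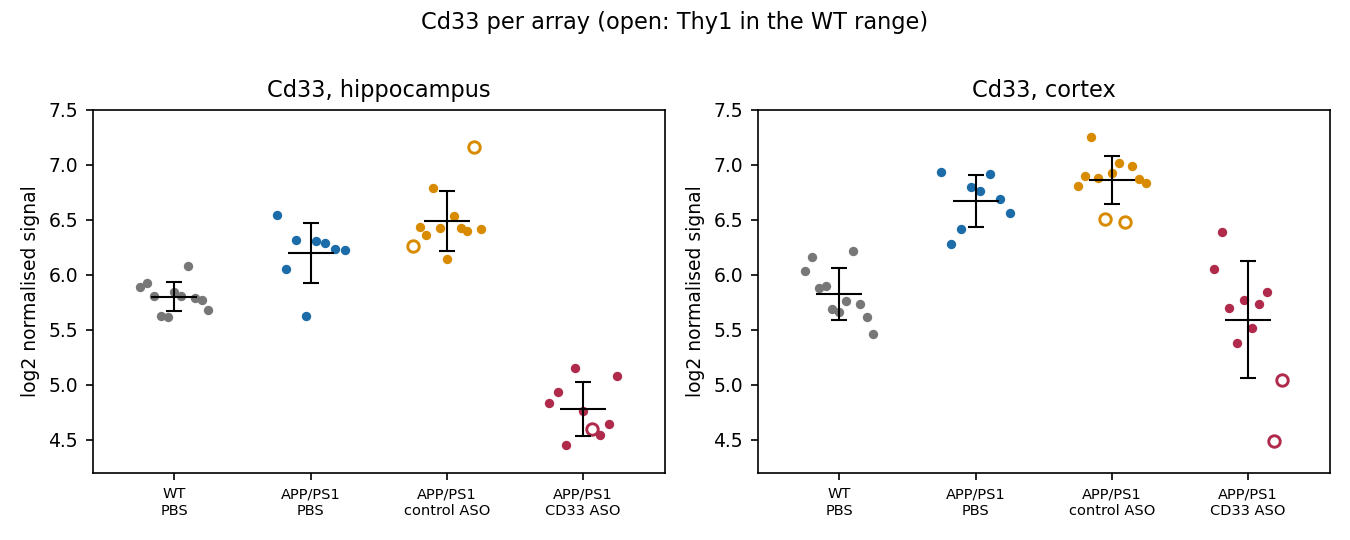
Cd33 as log2 signal (vertical axis) in each group (horizontal axis), with 1 panel per tissue, 1 point per array and bars for the mean ± SD; open circles mark the animals labelled APP/PS1 with Thy1 at or below the highest WT value. The 9 hippocampal arrays with CD33 ASO, at 4.78 ± 0.243, lay below all arrays with control ASO or PBS.

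The comparison of APP/PS1 with WT mice, both given PBS (n = 8 and n = 11), shows the state of the tissue on which the oligonucleotides acted. In the hippocampus microglial genes made up the largest rises. Cst7 rose by 2.94 (SE 0.246, adjusted p = 1.77e-11). It was detected on 8 of 8 APP/PS1 and 0 of 11 WT arrays, and was at least 5.46-fold higher. The chemokine genes Ccl4 and Ccl3 rose by 2.51 (SE 0.196) and 2.41 (SE 0.156), the leukocyte surface gene Cd52 by 1.79 (SE 0.166), Tyrobp, the adaptor of TREM2, by 1.44 (SE 0.151) and Trem2, a lipid-binding receptor of microglia, by 1.42 (SE 0.143). Gfap, the intermediate filament of astrocytes, rose by 1.05 (SE 0.153, adjusted p = 1.5e-05). Few genes fell, among them Plppr3 by 0.55 (SE 0.128, adjusted p = 0.0134) and the proteasome activator gene Psme2 by 0.40 (SE 0.103, adjusted p = 0.0418, -0.37 with slide as a block, adjusted p = 0.0721).

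Of 27 measured genes of the plaque-associated microglia list, 11 rose and 0 fell in the hippocampus (16 adjusted over the list alone). The median of the list was 0.34 (0.32 with slide as a block), with a camera adjusted p of 6.23e-43, and of 0.000179 with an estimated correlation. Complement and Fc receptor genes rose in 7 of 10 cases (9 adjusted over the list alone), among them C4b by 0.99, the immunoglobulin receptor chain gene Fcer1g by 0.93 and C1qb by 0.81. Their median was 0.79 (0.79 with slide as a block), with an adjusted p of 8.25e-27, and of 0.000591 with an estimated correlation. The homeostatic microglia list did not fall. In it 7 of 17 genes rose (11 adjusted over the list alone), such as Aif1 by 0.76 and Siglech by 0.71, while P2ry12 gave 0.25 (SE 0.171, adjusted p = 0.762) and Tmem119 0.20 (SE 0.117, adjusted p = 0.677). Its median was 0.32 (0.34 with slide as a block), with an adjusted p of 3.11e-21, and of 0.00128 with an estimated correlation. In the interferon response list 7 of 22 genes rose (14 adjusted over the list alone), with Ifi27l2a at 1.36 and Oasl2 at 0.87. Its median was 0.35 (0.35 with slide as a block), with an adjusted p of 6.44e-20, and of 0.00154 with an estimated correlation.

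Cytokine and Toll-like receptor genes, among them Ccl12 and Cd14, rose in 5 of 13 cases in the hippocampus (7 adjusted over the list alone, median 0.45, 0.44 with slide as a block). ITAM and ITIM signalling genes, among them Lat2 and Ptpn6, rose in 5 of 14 cases (9 adjusted over the list alone, median 0.35, 0.35 with slide as a block). Phagosome and lysosome genes, among them the cathepsin gene Ctsz, rose in 6 of 17 cases (12 adjusted over the list alone, median 0.30, 0.33 with slide as a block). Of the Alzheimer risk loci, Trem2 and Abi3 rose (2 of 19, 4 adjusted over the list alone, median 0.0591, 0.0803 with slide as a block). With an estimated correlation these 4 lists had adjusted p between 0.000364 and 0.00732.

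Among reactive astrocyte genes of the hippocampus Gfap and Aspg rose (2 of 18, 5 adjusted over the list alone, median 0.21, 0.21 with slide as a block). The list had an adjusted p of 3.99e-06, and of 0.0999 with an estimated correlation (0.0356 without the 4 animals). In antigen presentation B2m rose and Psme2 fell (3 up and 1 down adjusted over the list alone, median 0.23, 0.20 with slide as a block, adjusted p = 0.126 with an estimated correlation). No gene passed in astrocyte identity (median 0.0891, 0.0834 with slide as a block), oligodendrocyte and myelin (median -0.11, -0.11 with slide as a block) or cholesterol synthesis (median 0.0789, 0.066 with slide as a block). These 3 lists were called with the preset correlation, and their adjusted p was between 0.206 and 0.41 with an estimated correlation. The medians had the stated direction on 3 of 3 slides, except astrocyte identity and oligodendrocyte and myelin with 2 of 3. With median centring the medians were 0.0309 for astrocyte identity, -0.18 for oligodendrocyte and myelin and 0.0347 for Alzheimer risk loci. Without background correction they were 0.66 for ITAM and ITIM signalling, 0.54 for interferon response, 0.98 for cytokines and Toll-like receptors and 0.46 for reactive astrocyte genes. The immediate early list was called without the 4 animals (0 of 12 genes passed, median -0.13, adjusted p = 0.00542, and 0.248 with an estimated correlation). Over all probes limma called 142 of 14923 in the hippocampus, 134 higher and 8 lower in APP/PS1 mice. With slide as a block the number was 141, of which 125 were shared. Without the 4 animals with low Thy1, which enter only through the variance, it was 173 and included all 142.

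In the cortex the same comparison (n = 8 and n = 11) gave larger changes in microglial genes. Cst7 rose by 4.55 (SE 0.472, adjusted p = 9.16e-10, at least 17.9-fold, with 0 of 11 WT arrays detected), Ccl4 by 4.27 (SE 0.284), Ccl3 by 4.01 (SE 0.325, at least 11.7-fold), Cd52 by 3.08 (SE 0.234), Trem2 by 2.43 (SE 0.252) and Tyrobp by 2.36 (SE 0.227). Clec7a, the pattern receptor dectin-1, rose by 2.08 (SE 0.235, at least 3.48-fold), Gfap by 2.26 (SE 0.185, adjusted p = 2.49e-12) and Apoe by 0.28 (SE 0.074, adjusted p = 0.016). Genes that fell included Npcd by 0.49 (SE 0.134), the cadherin gene Cdh12 by 0.48 (SE 0.122), Wnt4 by 0.43 (SE 0.115) and Psme2 by 0.42 (SE 0.122), with adjusted p between 0.00987 and 0.0332. Each of these cortical genes passed with slide as a block.

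The plaque-associated microglia list had 22 of 27 genes up and 0 down in the cortex (23 adjusted over the list alone). Its median was 1.03 (1.03 with slide as a block), with an adjusted p of 7.56e-49, and of 0.000105 with an estimated correlation. Homeostatic microglia genes rose in 14 of 17 cases (16 adjusted over the list alone, median 0.85, 0.83 with slide as a block), among them P2ry12 by 0.65, Tmem119 by 0.76 and the fractalkine receptor gene Cx3cr1 by 1.13. Complement and Fc receptor genes rose in 9 of 10 cases (9 adjusted over the list alone, median 1.51, 1.52 with slide as a block), with C4b at 1.98. Phagosome and lysosome genes rose in 14 of 16 cases (16 adjusted over the list alone, median 0.79, 0.80 with slide as a block), with Ctsz at 1.62. ITAM and ITIM signalling genes rose in 11 of 13 cases (11 adjusted over the list alone, median 0.91, 0.91 with slide as a block), with Ptpn6 at 1.73. Cytokine and Toll-like receptor genes rose in 8 of 14 cases (10 adjusted over the list alone, median 0.87, 0.92 with slide as a block), with Tlr2 at 1.83. Interferon response genes rose in 13 of 22 cases (19 adjusted over the list alone, median 0.73, 0.75 with slide as a block), with Ifi27l2a at 2.70. Alzheimer risk locus genes rose in 9 of 19 cases (9 up and 1 down adjusted over the list alone, median 0.19, 0.17 with slide as a block), with Abi3 at 1.23. Reactive astrocyte genes rose in 6 of 16 cases (7 adjusted over the list alone, median 0.20, 0.25 with slide as a block), with Serpina3n at 1.41. With an estimated correlation the last 8 lists had adjusted p between 0.00019 and 0.0117.

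The other cortical lists passed only with the preset correlation when all animals were in the model. In antigen presentation 5 of 15 genes rose, such as H2-D1 by 0.64, and Psme2 fell (11 up and 1 down adjusted over the list alone, median 0.59, 0.62 with slide as a block, adjusted p = 0.156 with an estimated correlation). Of its 15 genes 10 rose and 1 fell without the 4 animals, and it passed with an estimated correlation (adjusted p = 0.00354). Fdps rose among cholesterol synthesis genes (median 0.15, 0.16 with slide as a block) and Mcm5 among proliferation genes (median 0.20, 0.23 with slide as a block). No gene passed in astrocyte identity (median 0.0855, 0.0806 with slide as a block) or among interneuron genes (median -0.19, -0.19 with slide as a block). These 4 lists had adjusted p between 0.11 and 0.168 with an estimated correlation. All 14 medians had the stated direction on 5 of 5 slides, except cholesterol synthesis with 4 of 5. The median of the plaque-associated list lay between 0.18 and 0.69 on 3 hippocampal slides and between 0.89 and 1.20 on 5 cortical slides. Without background correction the medians of the interferon and the cytokine lists were 1.19 and 1.82. Immediate early genes were called without the 4 animals (0 of 12 passed, median -0.14, adjusted p = 0.0285, and 0.425 with an estimated correlation). Limma called 609 of 14581 cortical probes, 534 higher and 75 lower. The number was 692 with slide as a block (586 shared) and 790 without the 4 animals (609 shared), and 1057 with both changes.

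**Figure D3:**
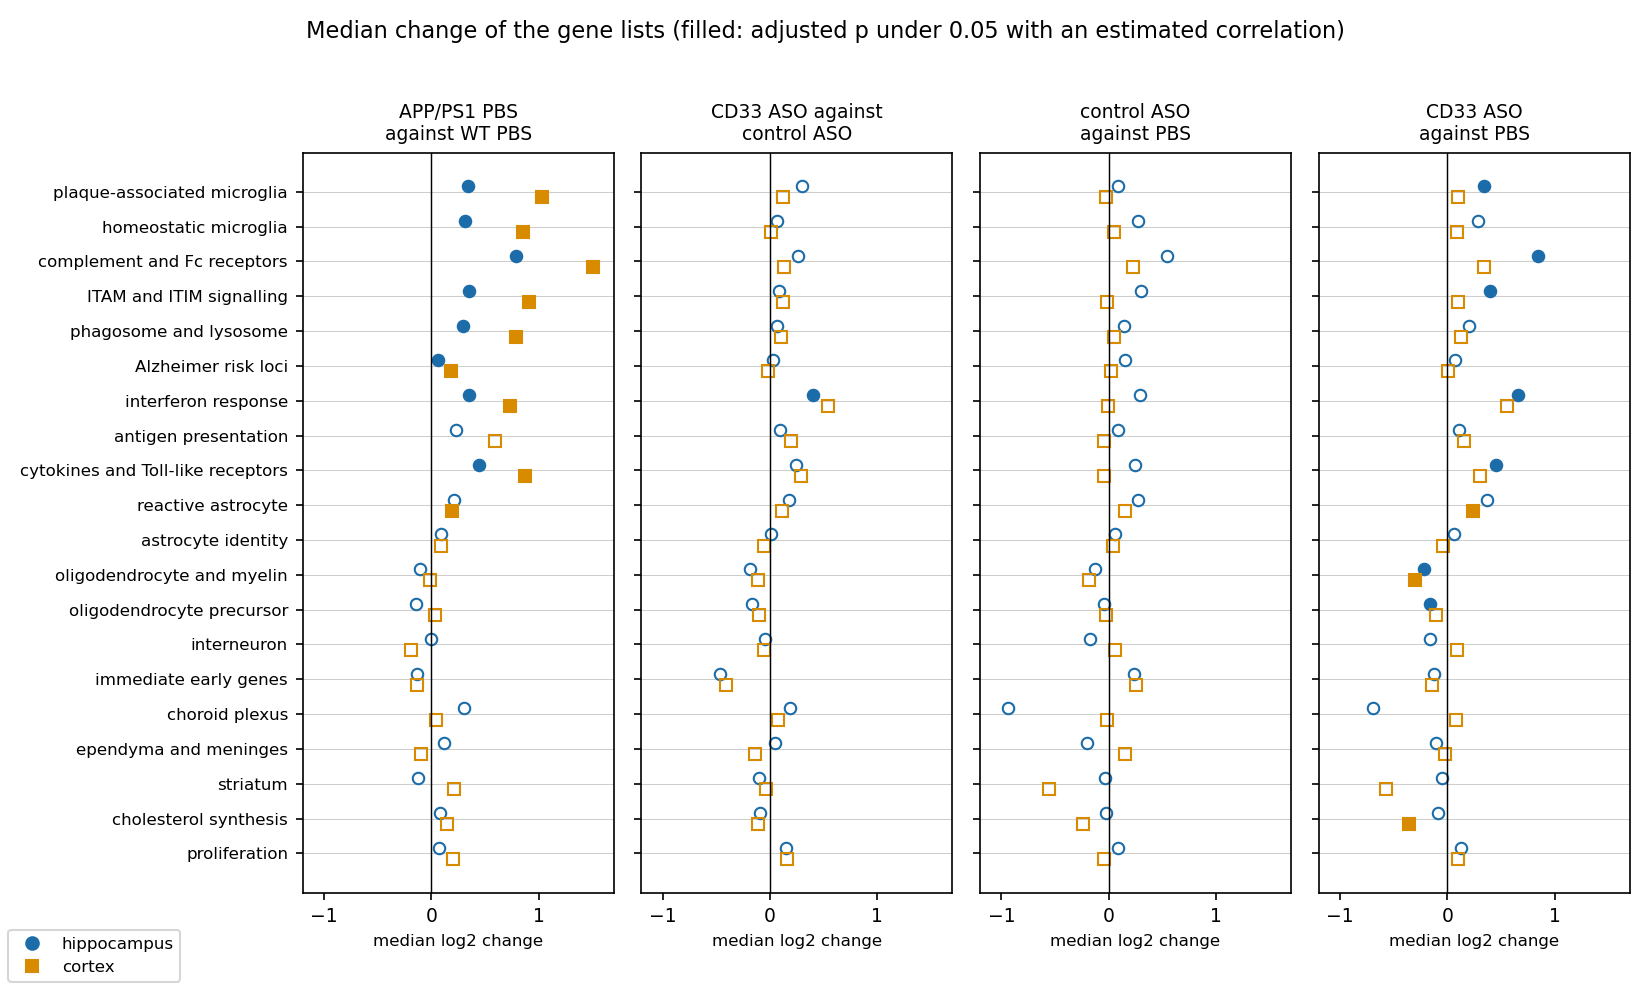
Median log2 difference (horizontal axis) of the genes of each list (vertical axis) in the 4 comparisons of each tissue, for the 20 lists with a camera adjusted p under 0.05 in any comparison. Filled points passed with an estimated correlation as well; the plaque-associated microglia list reached 0.34 in the hippocampus and 1.03 in the cortex for genotype.

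The comparison of CD33 ASO with control ASO, both in mice labelled APP/PS1, sets the targeting oligonucleotide against another oligonucleotide infusion, which had changes of its own. In the hippocampus (n = 9 and n = 11) the largest rise was that of Avil, which codes for the actin-binding protein advillin, by 2.45 (SE 0.154, adjusted p = 1.08e-15, 2.41 with slide as a block, higher on 3 of 3 slides). The interferon-induced genes Ifi27l2a, Oasl2 and Isg15 rose by 1.14 (SE 0.213), 0.82 (SE 0.131) and 0.78 (SE 0.149), the Fc receptor gene Fcgr4 by 1.14 (SE 0.261) and Ccl3 by 0.76 (SE 0.151). Next to Cd33, the largest falls that held with slide as a block were those of Fcna, a soluble lectin of macrophages, by 1.21 (SE 0.132), Cort, a neuropeptide of interneurons, by 0.94 (SE 0.204, on 1 of its 2 probes), Dnajc10, a chaperone of the endoplasmic reticulum, by 0.83 (SE 0.0646, on 1 of its 2 probes) and the myelin genes Hapln2 by 0.81 (SE 0.103) and Mog by 0.77 (SE 0.122). Fcna was 6.68 with control ASO, 5.47 with CD33 ASO and 4.88 with PBS, so its fall was from a level that control ASO had raised. These 11 genes had adjusted p of 0.00899 or lower, and 0.0424 or lower with slide as a block.

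The interferon response list stood out in the hippocampus, with 11 of 22 genes up and 0 down (18 adjusted over the list alone, 8 with slide as a block). Its median was 0.40 (0.42 with slide as a block, and 0.28 to 0.43 on 3 slides), with an adjusted p of 4.82e-17, and of 0.0185 with an estimated correlation. Of the 22 genes 5 passed without the 4 animals with low Thy1 (median 0.43, adjusted p = 0.0239 with an estimated correlation). Besides the genes above, Usp18 at 0.73 and Cxcl10 at 0.68 passed, but not without these animals (adjusted p = 0.0578 and 0.0526). All other list calls in this comparison ended with an estimated correlation. Of the plaque-associated microglia list 6 of 27 genes rose (13 up and 2 down adjusted over the list alone, 2 up with slide as a block), among them Ccl4 by 0.84, Tyrobp by 0.58 and Clec7a by 0.53 (1 of its 3 probes). The median of this list was 0.30 (0.25 with slide as a block), with an adjusted p of 2.03e-08, and of 0.2 with an estimated correlation. Trem2, at 0.38 (SE 0.139, adjusted p = 0.113), Cst7, at 0.31 (SE 0.238, adjusted p = 0.516), and Gfap, at 0.27 (SE 0.148, adjusted p = 0.324), did not pass. Without the 4 animals Ccl4 (adjusted p = 0.0668), Tyrobp (0.0722) and Clec7a (0.105) no longer passed. With slide as a block Tyrobp (0.40, adjusted p = 0.287) and Clec7a (0.63, adjusted p = 0.09) did not pass either.

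Of the complement and Fc receptor genes Fcgr4 and C4b rose (2 of 10, 5 adjusted over the list alone, median 0.26, 0.31 with slide as a block, adjusted p = 0.301 with an estimated correlation). Cytokine and Toll-like receptor genes rose in 4 of 13 cases (4 adjusted over the list alone, 3 with slide as a block, 2 without the 4 animals, median 0.24, 0.26 with slide as a block, adjusted p = 0.2 with an estimated correlation). The myelin genes Mog, Mal, Cldn11 and Cnp fell (4 of 12 genes of the oligodendrocyte and myelin list, 8 adjusted over the list alone, 2 with slide as a block). The median of this list was -0.19 (-0.17 with slide as a block), with an adjusted p of 0.177 with an estimated correlation. Of the immediate early genes Egr1 fell by 0.46 (1 of 12, 8 adjusted over the list alone, 0 with slide as a block), a call that was lost without the 4 animals (adjusted p = 0.0534). Their median was -0.46 (-0.41 with slide as a block, -0.25 without the 4 animals), with an adjusted p of 0.423 with an estimated correlation. Psmb9, Tap2 and B2m rose among antigen presentation genes (median 0.0885, 0.0887 with slide as a block, adjusted p = 0.645 with an estimated correlation), of which Psmb9 (adjusted p = 0.101) and B2m (0.137) did not pass with slide as a block. No phagosome and lysosome gene passed (5 up and 1 down adjusted over the list alone, median 0.0642, 0.0914 with slide as a block, adjusted p = 0.707 with an estimated correlation). The medians had the stated direction on 3 of 3 slides for the interferon, plaque-associated, cytokine and immediate early lists, on 2 of 3 for complement, antigen presentation and oligodendrocyte genes and on 1 of 3 for phagosome genes. The medians of the phagosome and antigen presentation lists were 0.16 and 0.19 without background correction and 0.0419 and 0.0548 with median centring. Leaving out the 4 animals, the reactive astrocyte (2 of 18 rose, adjusted p = 8.35e-05), ITAM and ITIM signalling (0.0169) and proliferation lists (0.0395) were called as well, but not with an estimated correlation. Among single genes, Plin4 at -1.18 and Vwf at -0.90 were called, but gave -0.83 (adjusted p = 0.396) and -0.70 (adjusted p = 0.22) with slide as a block. Limma called 527 of 14923 probes, 269 higher and 258 lower with CD33 ASO. With slide as a block 113 were called (102 shared), without the 4 animals 221 (199 shared), and with both changes 92. Without CD33 ASO replicate 4, 9 or 6 the number was 326, 327 or 329.

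In the cortex (n = 10 and n = 11) Avil again had the largest rise, by 2.27 (SE 0.172, adjusted p = 8.17e-13, 2.37 with slide as a block, higher on 4 of 4 slides). Rises that also held without the 4 animals and with slide as a block were those of Sh3d21 by 0.64 (SE 0.128), Aspdh by 0.62 (SE 0.102), Rassf4 by 0.54 (SE 0.103) and Czib by 0.50 (SE 0.0738). Czib was 9.57 with CD33 ASO, 9.08 with control ASO and 9.61 with PBS, so the group apart from PBS was that with control ASO. Falls that held in both ways, besides Cd33, were those of Fcna by 0.94 (SE 0.137), Mog by 0.64 (SE 0.111), the endothelial gene Vwf by 0.57 (SE 0.105), Ddah1 by 0.32 (SE 0.0637) and, on 1 of 2 probes each, Dnajc10 by 0.36 (SE 0.0432) and Ncam1 by 0.32 (SE 0.0582). Fcgr4 rose by 1.43 (SE 0.28, adjusted p = 0.00418) and the formyl peptide receptor gene Fpr2 by 1.13 (SE 0.23, adjusted p = 0.00684), but without the 4 animals their adjusted p was 0.132 and 0.0543. The macrophage gene Mrc1 fell by 0.53 (SE 0.113, adjusted p = 0.0114) and did not pass with slide as a block (-0.47, adjusted p = 0.0724) or without the animals (adjusted p = 0.0968). Trem2, at -0.0293 (SE 0.237, adjusted p = 0.984), Tyrobp, at 0.12 (SE 0.213, adjusted p = 0.905), and Gfap, at 0.19 (SE 0.174, adjusted p = 0.791), did not pass.

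No single gene of the interferon response list passed in the cortex over all probes (0 of 22 by limma), while 19 passed adjusted over the list alone, all higher with CD33 ASO. The list had a median of 0.54 (0.55 with slide as a block, above 0 on 4 of 4 slides), with an adjusted p of 6.12e-19, and of 0.114 with an estimated correlation. Without the 4 animals its median was 0.31 (adjusted p = 1e-15, and 0.106 with an estimated correlation). The myelin genes Mog and Mal fell (2 of 12, 3 adjusted over the list alone), of which Mal did not pass with slide as a block (-0.26, adjusted p = 0.366) or without the 4 animals (adjusted p = 0.175). The median of the oligodendrocyte and myelin list was -0.115 (-0.15 with slide as a block, below 0 on 3 of 4 slides), with an adjusted p of 1.27e-06, and of 0.114 with an estimated correlation. The other 7 list calls had adjusted p between 0.386 and 0.589 with an estimated correlation. The medians were -0.41 for immediate early genes (-0.37 with slide as a block), -0.11 for cholesterol synthesis (-0.17), -0.14 for ependyma and meninges (-0.12), 0.13 for complement and Fc receptors (0.22), 0.19 for antigen presentation (0.16), 0.29 for cytokines and Toll-like receptors (0.28) and 0.16 for proliferation (0.17). The complement, antigen presentation, ependyma and proliferation lists were no longer called without the 4 animals (adjusted p between 0.0653 and 0.883, medians 0.0573, 0.0509, -0.0117 and 0.0784). The medians of immediate early, cytokine and cholesterol synthesis genes were then -0.22, 0.16 and -0.0722, and the reactive astrocyte list was called (adjusted p = 0.0138). With median centring the medians were 0.0619 for complement and -0.18 for both the oligodendrocyte and the cholesterol list, and without background correction 0.25 for proliferation. Limma called 47 of 14581 probes, 27 higher and 20 lower (57.4% higher, but 37.8% of 37 with median centring). The number was 37 with slide as a block (33 shared), 28 without the 4 animals (24 shared) and 45 with both changes.

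**Figure D4:**
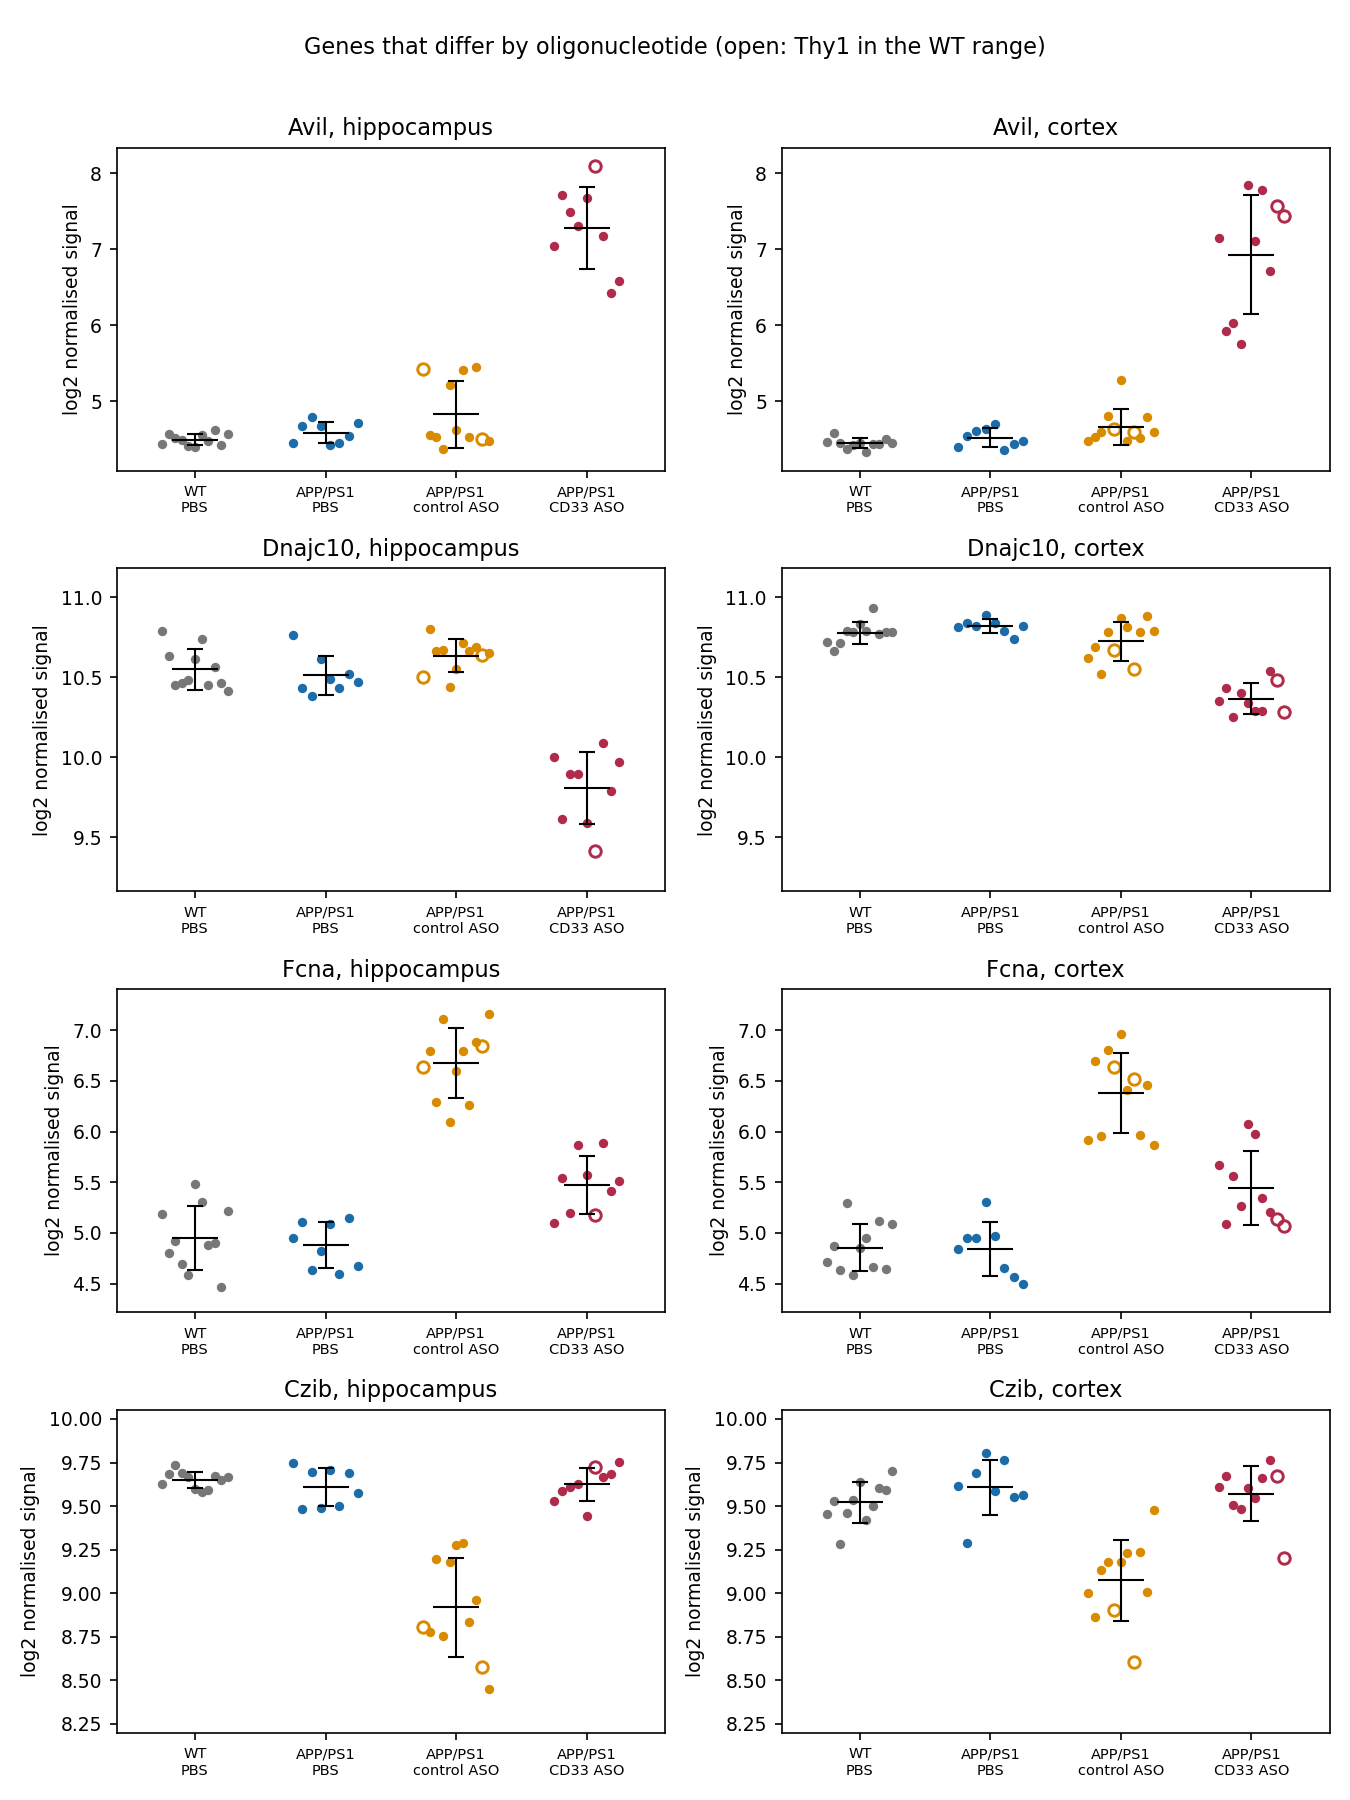
Log2 signal (vertical axis) of Avil, Dnajc10, Fcna and Czib in each group (horizontal axis) of both tissues, with 1 point per array and bars for the mean ± SD. Avil lay between 6.43 and 8.09 on the hippocampal arrays with CD33 ASO and between 4.37 and 5.45 on all other hippocampal arrays.

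The comparison of control ASO with PBS shows the response to an oligonucleotide that does not target Cd33. In the hippocampus (n = 11 and n = 8) the lipid droplet gene Plin4 rose by 2.48 (SE 0.349, adjusted p = 2.43e-05), Fcna by 1.80 (SE 0.137, adjusted p = 1.97e-12), the galectin gene Lgals3 by 1.41 (SE 0.245), the phagocyte gene Gpnmb by 1.21 (SE 0.21), Wfdc17 by 1.11 (SE 0.159) and the cell cycle inhibitor gene Cdkn1a by 1.08 (SE 0.19). The myelin gene Opalin fell by 0.96 (SE 0.144), the potassium channel partner gene Kcnip4 by 0.79 (SE 0.165) and Ninj2 by 0.78 (SE 0.116). The blood genes Hbb-bt, Alas2 and Hba-a1 fell by 1.72 (SE 0.286), 1.26 (SE 0.29) and 0.77 (SE 0.243). All these genes passed with slide as a block except Alas2 (adjusted p = 0.0825) and Hba-a1 (0.277).

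Complement and Fc receptor genes rose in 8 of 10 cases in the hippocampus (10 adjusted over the list alone, 1 with slide as a block). Their median was 0.54 (0.41 with slide as a block), with an adjusted p of 6.09e-08, and of 0.305 with an estimated correlation. Examples were Fcgr4 by 1.21 (1.03 with slide as a block, adjusted p = 0.1), C1qb by 0.69 (adjusted p = 0.0625 with slide as a block) and C1qa by 0.59. Homeostatic microglia genes rose in 5 of 17 cases (8 adjusted over the list alone, 1 with slide as a block, median 0.27, 0.13 with slide as a block), such as Tmem119 by 0.58 (adjusted p = 0.0553 with slide as a block) and the phagocytic receptor gene Mertk by 0.58. ITAM and ITIM signalling genes rose in 6 of 14 cases (8 adjusted over the list alone, 1 with slide as a block, median 0.30, 0.27 with slide as a block), with Dok3, the 1 that kept its call, at 0.44. Interferon response genes rose in 4 of 22 cases (8 adjusted over the list alone, 0 with slide as a block, median 0.29, 0.25 with slide as a block), with Ifitm3 at 0.53 (adjusted p = 0.123 with slide as a block). Cytokine and Toll-like receptor genes rose in 3 of 13 cases (4 adjusted over the list alone, 1 with slide as a block, median 0.25, 0.16 with slide as a block), with Tlr7, which kept its call, at 0.75. Alzheimer risk locus genes rose in 3 of 19 cases (5 adjusted over the list alone, 0 with slide as a block, median 0.15, 0.0923 with slide as a block), with Ms4a6d at 1.19 (0.92 with slide as a block, adjusted p = 0.0802). The last 5 lists had an adjusted p of 0.305 with an estimated correlation. Phagosome and lysosome genes rose in 3 of 17 cases (5 adjusted over the list alone, 1 with slide as a block, median 0.14, 0.14 with slide as a block, 0.25 with median centring, adjusted p = 0.699 with an estimated correlation).

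The interneuron genes Sst, Npy, Gad1 and Slc32a1 fell in the hippocampus with control ASO (4 of 9, 5 adjusted over the list alone, 0 with slide as a block). The median of their list was -0.18 (-0.0961 with slide as a block, -0.0374 with median centring), with an adjusted p of 0.305 with an estimated correlation. Opalin, Cnp and Mag fell among oligodendrocyte and myelin genes (3 of 12, 3 adjusted over the list alone, median -0.13, -0.15 with slide as a block, -0.0306 with median centring, adjusted p = 0.493 with an estimated correlation). Of the 3 only Opalin passed with slide as a block, and only Opalin without the 4 animals. The choroid plexus list had a median of -0.94 (-0.47 with slide as a block, 0 of 7 genes passed, adjusted p = 0.0167, and 0.699 with an estimated correlation). Ttr, the main transcript of choroid plexus, gave -1.2 (SE 0.468, adjusted p = 0.0848). The choroid plexus list was no longer called without the 4 animals (median -0.61, adjusted p = 0.101), and the plaque-associated list was (median 0.18, adjusted p = 0.035, and 0.71 with an estimated correlation). The medians of the 10 lists had the stated direction on 2 of 2 slides. Limma called 1698 of 14923 probes, 855 higher and 843 lower (50.4% higher, but 82.1% of 1634 with median centring). With slide as a block 121 were called (111 shared), and 2 slides held both groups. Without the 4 animals 1232 were called (1139 shared), and with both changes 80. Without PBS replicate 7 or 8 the number was 1129 or 1131.

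In the cortex (n = 11 and n = 8) Plin4 rose by 2.30 (SE 0.338), Lgals3 by 1.98 (SE 0.275), Fcna by 1.54 (SE 0.146, adjusted p = 1.61e-09), Gpnmb by 1.24 (SE 0.189), Wfdc17 by 1.13 (SE 0.143) and the macrophage gene Ms4a7 by 1.08 (SE 0.149). Opalin fell by 0.93 (SE 0.148), Enpp6, a gene of newly formed oligodendrocytes, by 0.77 (SE 0.143), Pllp by 0.64 (SE 0.086) and Alas2 by 1.48 (SE 0.336). These 10 genes passed with slide as a block. Opalin, Cnp and Mag fell among oligodendrocyte and myelin genes (3 of 12, 5 adjusted over the list alone, median -0.18, -0.17 with slide as a block). Mag did not pass without the 4 animals (adjusted p = 0.065). The list had an adjusted p of 4.69e-06, and of 0.132 with an estimated correlation. The cholesterol synthesis genes Dhcr7 and Hmgcs1 fell (2 of 9, 7 adjusted over the list alone, 0 with slide as a block), and Dhcr7 did not pass without the 4 animals (adjusted p = 0.0829). The median of their list was -0.24 (-0.20 with slide as a block), with an adjusted p of 0.132 with an estimated correlation. No gene passed in the complement and Fc receptor (median 0.23, 0.21 with slide as a block), reactive astrocyte (median 0.15, 0.16 with slide as a block) and immediate early lists (median 0.25, 0.30 with slide as a block). These 3 lists were called with the preset correlation and had adjusted p between 0.151 and 0.687 with an estimated correlation. The immediate early genes were no longer called without the 4 animals (median -0.0428, adjusted p = 0.907), and 3 of 10 complement and Fc receptor genes rose (median 0.40, adjusted p = 1.27e-11). The lists of plaque-associated (median 0.0959, adjusted p = 6.45e-06) and homeostatic microglia (0.18, 3.81e-09), phagosome and lysosome (0.17, 2.56e-08), ITAM and ITIM signalling (0.13, 0.00139), Alzheimer risk loci (0.0708, 0.00287) and p53 targets (0.14, 0.044) were then called as well. With all animals the medians of these 6 lists were -0.0283, 0.047, 0.0478, -0.0165, 0.0195 and 0.12, so those of the plaque-associated and the ITAM and ITIM lists turned from negative to positive. None of the 6 and the complement list passed with an estimated correlation (adjusted p between 0.0748 and 0.216). Markers of striatum, a region next to the cortex, had a median of -0.56 (-0.51 with slide as a block, 0 of 7 passed, 3 lower adjusted over the list alone, adjusted p = 0.000133, and 0.416 with an estimated correlation). The medians had the stated direction on 5 of 5 slides, except immediate early genes with 3 of 5. Limma called 135 of 14581 probes, 53 higher and 82 lower. The number was 127 with slide as a block (106 shared) and 142 without the 4 animals (106 shared), and 162 with both changes.

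CD33 ASO against PBS holds any response to an oligonucleotide together with that to the targeting sequence, and cannot separate them. Whether such responses add up was not tested. In the hippocampus (n = 9 and n = 8) Avil rose by 2.69 (SE 0.166, at least 4.74-fold, as it was detected on 0 of 8 PBS arrays), Fcgr4 by 2.34 (SE 0.282), Lgals3 by 1.85 (SE 0.256), Wfdc17 by 1.53 (SE 0.166), Ifi27l2a by 1.50 (SE 0.23), Gpnmb by 1.44 (SE 0.22) and Oas2 by 1.27 (SE 0.139). Trem2 rose by 0.68 (SE 0.15, adjusted p = 0.00281), Tyrobp by 0.78 (SE 0.158, adjusted p = 0.00118) and Tmem119 by 0.58 (SE 0.122, adjusted p = 0.00184). Besides Cd33, Cort fell by 1.60 (SE 0.22), Opalin by 1.38 (SE 0.15), Crhbp by 0.96 (SE 0.152), the cold-inducible gene Rbm3 by 0.96 (SE 0.158, on 1 of its 2 probes), Enpp6 by 0.92 (SE 0.159) and Mog by 0.91 (SE 0.132). The blood genes Alas2, Hbb-bt and Hba-a1 fell by 1.49, 1.46 and 1.03. Each of these genes passed with slide as a block.

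Interferon response genes rose in 17 of 22 cases in the hippocampus (21 adjusted over the list alone, 16 with slide as a block), among them Usp18 by 1.19 and Isg15 by 1.13. Their median was 0.66 (0.69 with slide as a block), with an adjusted p of 7.37e-31, and of 0.000396 with an estimated correlation. Complement and Fc receptor genes rose in 9 of 10 cases (10 adjusted over the list alone, median 0.84, 0.79 with slide as a block), with C1qa at 0.98. Cytokine and Toll-like receptor genes rose in 7 of 13 cases (11 adjusted over the list alone, median 0.45, 0.48 with slide as a block), with Ccl4 at 1.09. ITAM and ITIM signalling genes rose in 8 of 14 cases (11 up and 1 down adjusted over the list alone, median 0.40, 0.38 with slide as a block), with Lat2 at 0.75. Plaque-associated microglia genes rose in 13 of 27 cases (16 up and 1 down adjusted over the list alone, median 0.34, 0.33 with slide as a block), with Cd52 at 0.82. These 4 lists had adjusted p between 0.00291 and 0.0429 with an estimated correlation. Oligodendrocyte and myelin genes fell in 7 of 12 cases, among them Opalin, Mog, Cnp and Mbp (8 adjusted over the list alone, 7 with slide as a block). Their median was -0.21 (-0.27 with slide as a block), with an adjusted p of 4.68e-13, and of 0.00442 with an estimated correlation. Of the oligodendrocyte precursor list Enpp6 fell (1 of 6, 2 adjusted over the list alone, median -0.16, -0.16 with slide as a block, adjusted p = 0.0429 with an estimated correlation).

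Other calls of this comparison ended with an estimated correlation, where their adjusted p lay between 0.109 and 0.298. Homeostatic microglia genes, such as Fcrls, rose in 5 of 17 cases (12 adjusted over the list alone, median 0.29, 0.22 with slide as a block). Reactive astrocyte genes, such as Lcn2 and Serpina3n, rose in 6 of 18 cases (9 up and 1 down adjusted over the list alone, median 0.37, 0.41 with slide as a block). Phagosome and lysosome genes, such as Ctsh and Grn, rose in 5 of 17 cases (7 adjusted over the list alone, median 0.20, 0.22 with slide as a block). Psmb8 and B2m rose in antigen presentation (2 of 15, 4 adjusted over the list alone, median 0.10, 0.16 with slide as a block). Npy, Sst and Slc32a1 fell among interneuron genes (3 of 9, 3 adjusted over the list alone, median -0.17, -0.10 with slide as a block). Hmgcs1 fell among cholesterol synthesis genes (1 of 9, 2 adjusted over the list alone, median -0.0832, -0.14 with slide as a block). The choroid plexus list had a median of -0.69 (-0.55 with slide as a block, adjusted p = 0.0574) beside these groups. The medians of the called lists had the stated direction on 4 of 4 slides, except homeostatic microglia and antigen presentation with 3 of 4 and interneuron genes with 2 of 4. Leaving out the 4 animals, homeostatic microglia (9 of 17 rose) and interneuron genes (4 of 9 fell) passed with an estimated correlation (adjusted p = 0.0388 each), the cholesterol synthesis median was -0.0497, and the immediate early list was called (median -0.16, adjusted p = 0.00515, and 0.262 with an estimated correlation). Without background correction the medians of antigen presentation and cytokine genes were 0.36 and 0.90. Limma called 740 of 14923 probes, 451 higher and 289 lower. The number was 787 with slide as a block (638 shared), 752 without the 4 animals (650 shared) and 639 with both changes.

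In the cortex (n = 10 and n = 8) Avil rose by 2.41 (SE 0.186, at least 3.56-fold, with 0 of 8 PBS arrays detected), Lgals3 by 2.24 (SE 0.281), Fcgr4 by 1.83 (SE 0.304), Wfdc17 by 1.4 (SE 0.146), Gpnmb by 1.03 (SE 0.193) and Oas2 by 0.94 (SE 0.179). Opalin fell by 1.03 (SE 0.151), Tnnc1 by 0.96 (SE 0.166), the choline transporter gene Slc5a7 by 0.93 (SE 0.213), Enpp6 by 0.88 (SE 0.146) and Alas2 by 1.47 (SE 0.343). Each of these genes passed with slide as a block.

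Oligodendrocyte and myelin genes fell in 6 of 12 cases in the cortex with CD33 ASO against PBS, among them Mog by 0.80 and Cnp by 0.50 (10 adjusted over the list alone, 6 with slide as a block). Their median was -0.30 (-0.30 with slide as a block), with an adjusted p of 7.93e-17, and of 0.00112 with an estimated correlation. Cholesterol synthesis genes fell in 5 of 9 cases, among them Insig1 by 0.54 and Hmgcs1 by 0.36 (8 adjusted over the list alone, 7 with slide as a block). Their median was -0.36 (-0.35 with slide as a block), with an adjusted p of 2.89e-13, and of 0.00474 with an estimated correlation. The reactive astrocyte genes Lcn2, Serpina3n and Hspb1 rose (3 of 16, 5 adjusted over the list alone, median 0.24, 0.25 with slide as a block, adjusted p = 0.0264 with an estimated correlation). The interferon response genes Oasl2, Ifitm3, Irf9 and Ifi27 rose (4 of 22, 13 adjusted over the list alone, 5 with slide as a block). The median of their list was 0.56 (0.55 with slide as a block), with an adjusted p of 3.57e-14, and of 0.152 with an estimated correlation. Fcgr4 rose among complement and Fc receptor genes (6 adjusted over the list alone, median 0.35, 0.39 with slide as a block), and Lgals3 and Gpnmb among plaque-associated microglia genes (2 adjusted over the list alone, median 0.10, 0.0502 with slide as a block). Enpp6 fell among oligodendrocyte precursor genes (1 adjusted over the list alone, median -0.10, -0.0759 with slide as a block). No gene passed in phagosome and lysosome (1 adjusted over the list alone, median 0.13, 0.11 with slide as a block) or cytokines and Toll-like receptors (median 0.31, 0.29 with slide as a block). These 5 lists had adjusted p between 0.155 and 0.719 with an estimated correlation. Striatum genes had a median of -0.57 (-0.64 with slide as a block, 0 of 7 passed, 6 lower adjusted over the list alone, adjusted p = 1.45e-05, and 0.197 with an estimated correlation) beside these groups. The medians had the stated direction on 4 of 4 slides, except striatum genes with 3 of 4 and oligodendrocyte precursor genes with 2 of 4.

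Without the 4 animals with low Thy1 more cortical lists passed for CD33 ASO against PBS. Interferon response genes then rose in 8 of 22 cases (median 0.45, adjusted p = 0.0376 with an estimated correlation) and complement and Fc receptor genes in 7 of 10 (median 0.44, adjusted p = 0.019 with an estimated correlation). The plaque-associated list had 4 of 27 genes up (median 0.17) and the phagosome and lysosome list 4 of 16 (median 0.15), each with an adjusted p of 0.0589 with an estimated correlation. Of the cytokine and Toll-like receptor genes 2 of 14 rose (median 0.21, adjusted p = 0.108 with an estimated correlation). Cholesterol synthesis genes fell in 3 of 9 cases in place of 5 (median -0.33, adjusted p = 0.0122 with an estimated correlation), and Lcn2 no longer passed (adjusted p = 0.0829). Homeostatic microglia (3 of 17 rose, median 0.19), ITAM and ITIM signalling (2 of 13 rose, median 0.17) and immediate early genes (0 of 12 passed, median -0.29) were called with the preset correlation, and had adjusted p between 0.108 and 0.274 with an estimated correlation. The oligodendrocyte precursor list was no longer called (median -0.00657, adjusted p = 0.156). With median centring and all animals, the medians of plaque-associated and phagosome genes were 0.0624 and 0.0723. Limma called 217 of 14581 probes, 100 higher and 117 lower. The number was 314 with slide as a block (199 shared), 320 without the 4 animals (180 shared) and 652 with both changes. Without CD33 ASO replicate 1 it was 140.

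The genes that genotype raised were then followed under CD33 ASO against control ASO, 2 comparisons that share no array. In the hippocampus the 108 genes raised by genotype had a median difference of 0.21 under CD33 ASO (quartiles 0.075 and 0.35, 0.25 with slide as a block), toward higher values. Of these genes 20 passed in the genotype direction, among them Ccl3, Ccl4, Oasl2 and C4b, and 0 against it (10 and 1, Cd33, of 110 genes with slide as a block), while 17.6% had a difference against the genotype. The same genes had a median of 0.23 without the 4 animals. Of them 12 passed along the genotype direction (11 of the 20, with Ccl3, Oasl2 and C4b) and 0 against it, while Ccl4, Tyrobp, Clec7a and Usp18 did not pass. The set gave a camera p of 1.06e-15, a p of 0.0885 with an estimated correlation and a fry p of 0.0207 (0.058 and 0.018 without the 4 animals). In the cortex the 406 genes had a median of 0.0897 (quartiles 0.0123 and 0.19, 0.0921 with slide as a block), with 21.2% against the genotype. Cd33 was the 1 gene that passed against the genotype direction and Fcgr4 the 1 that passed along it. Leaving out the 4 animals gave a median of 0.0443, with 33.5% against the genotype, and 0 genes passed along it. The cortical set gave a camera p of 2.12e-08, a p of 0.314 with an estimated correlation and a fry p of 0.224. The genes lowered by genotype had medians of -0.0391 (5 genes) and -0.0412 (45 genes).

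**Figure D5:**
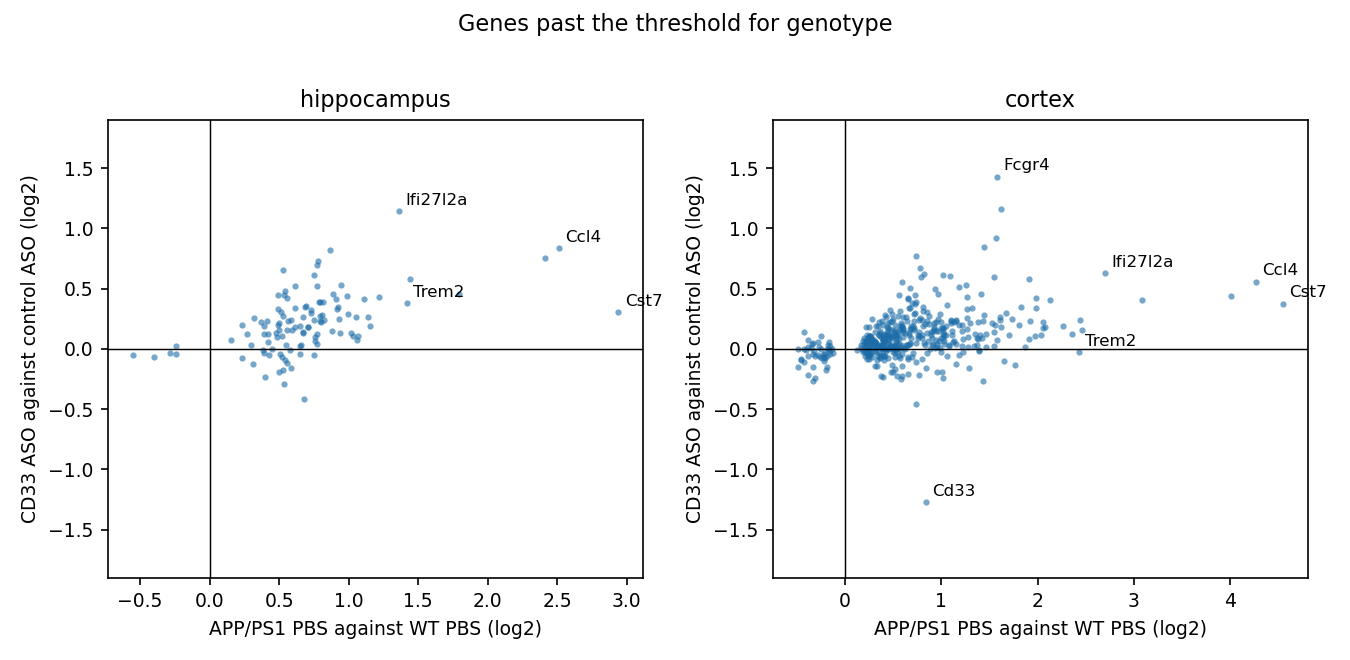
Log2 difference for CD33 ASO against control ASO (vertical axis) against the log2 difference for genotype (horizontal axis), with 1 point per gene called for genotype and 1 panel per tissue. The genes raised by genotype had a median of 0.21 in the hippocampus and 0.0897 in the cortex on the vertical axis.

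The same animals gave both tissues, so the size of each effect was compared between them. The genotype effect differed for 49 of 15290 probes, of which 46 were more positive in the cortex. C4b rose by 0.99 in the hippocampus and 1.98 in the cortex (difference -0.995, SE 0.176, adjusted p = 0.000987), Serpina3n gave 0.30 and 1.41 (difference -1.11, SE 0.192, adjusted p = 0.000987), Ccl4 2.51 and 4.27 (-1.76, SE 0.343, adjusted p = 0.0042) and Gfap 1.05 and 2.26 (-1.2, SE 0.24, adjusted p = 0.00559). Plppr3 gave -0.55 and 0.27 (-0.82, SE 0.171, adjusted p = 0.011). The CD33 ASO effect against control ASO differed for 1 probe, that of Dnajc10, which fell by 0.83 in the hippocampus and 0.36 in the cortex (difference -0.47, SE 0.0741, adjusted p = 0.000174), with 1403 probes at an unadjusted p under 0.05. The control ASO effect against PBS differed for 31 probes and that of CD33 ASO against PBS for 19, among them Cort at -1.60 in the hippocampus (difference -1.33). Cd33 itself gave a difference of -0.44 (SE 0.17, adjusted p = 0.383) and Avil 0.19 (SE 0.222, adjusted p = 0.834). With CD33 ASO the hippocampal Cd33 level lay close to background, which limits the fall that could be seen there. The lack of a call for Cd33 therefore does not show equal falls. Tissue and slide were confounded in this comparison, and with slide as a block 11 and 0 probes were called for genotype and CD33 ASO.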

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

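Of the tests in this part, the exchange with wild-type animals, the genotype genes of the low-Thy1 animals, the slide block for Avil, Dnajc10, Fcna and Czib and the genotype change of these genes were chosen only after the result was seen, and the settings without the low-Thy1 animals and with a choroid plexus covariate after the data had been seen.

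Groups of 11 arrays, which are WT PBS and control ASO in both tissues, were not tested for an array far from the others. In the other groups such an array was found 9 times in 56 groups of values. Chance alone gives about 1 in 20 for independent values, while values of the same arrays are related. In the hippocampus these were Ttr at 12.98 on PBS replicate 2 (lowest, next 14.04), Thy1 at 13.92 on CD33 ASO replicate 6 (lowest, next 14.59), Gfap at 11.23 on CD33 ASO replicate 4 (highest, next 10.58) and P2ry12 at 4.7 on CD33 ASO replicate 3 (lowest, next 5.432). In the cortex they were Clec7a at 6.198 on PBS replicate 2 (lowest, next 6.765), Cst7 at 5.895 and Clec7a at 5.192 on CD33 ASO replicate 9 (both lowest, next 8.042 and 6.8), 13136 probes detected on CD33 ASO replicate 6 (next 13422) and a mean correlation with the group of 0.9801 on CD33 ASO replicate 10 (next 0.9865). Cortical CD33 ASO replicates 9 and 10 and hippocampal replicate 6 belong to animals with Thy1 at or below the highest WT value.

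Effects that differed between hippocampus and cortex were found for 49 probes for genotype, 1 for CD33 ASO against control ASO, 31 for control ASO against PBS and 19 for CD33 ASO against PBS. For genotype 46 of the 49 were more positive in the cortex, among them C4b, Serpina3n, Ccl4 and Gfap. Of 100 splits of the animals, 1 gave a count as large for genotype (real value 49, highest other 1). The splits also removed the genotype effect common to both tissues, so they cannot test chance for the difference between tissues alone. The count was lower with slide as a block and with median centring. For CD33 ASO against control ASO, 5 of 100 splits did (real value 1, highest other 6), so chance cannot be excluded for that count.

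Thy1 lay at the WT level in 4 animals labelled APP/PS1, on 7 arrays. An exchange with WT animals is argued against by 0 of 22 arrays labelled WT reaching the lowest APP/PS1 PBS array. Less neuronal RNA is argued against by a median deviation of 0.0509 of the neuron list on these arrays, against a fall in Thy1 of 0.68 to 0.88. Animals without the transgene under a transgenic label stay open as a candidate explanation, as the genotype genes had a median below the others of the group on 6 of 7 arrays, but by more than the SD of the others on 4 of them, and by -0.000985 on cortical CD33 ASO replicate 10. The arrays of 1 animal went apart, with 0.30 in the hippocampus (control ASO replicate 10) and -0.62 in the cortex (control ASO replicate 5), Cst7 lay above the WT range on 6 of the 7 arrays, and since no WT animal received an oligonucleotide, the level expected without the transgene was not measured.

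In the hippocampus 1698 probes were called for control ASO against PBS and 121 with slide as a block, where the SE was 1.12 times and the log2 difference of called probes 0.61 times as large. Animals with low Thy1 are argued against as the whole cause by 1232 calls without them. With a choroid plexus covariate 1029 probes were called. The choroid plexus list itself had a median of -0.94 between these groups, so such a covariate can remove calls whatever their cause. Leaving out PBS replicate 7 alone gave 1129. A part played by choroid plexus in the dissected tissue is therefore neither shown nor excluded. The unequal spread of groups over slides cannot be told apart from the oligonucleotide for the lost probes, of which 67.7% had the same direction in the cortex, against 96.4% of the kept and 54.7% of all probes, since only 2 slides held both groups.

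Avil rose and Dnajc10 fell under CD33 ASO, and Fcna rose and Czib fell under control ASO, in both tissues. Dnajc10 fell on 1 of its 2 probes. Fcna also lay higher with CD33 ASO than with PBS, at 5.47 against 4.88 in the hippocampus and 5.44 against 4.84 in the cortex. A higher Fcna was therefore not confined to control ASO. The spread over slides is argued against by 8 of 8 changes past the threshold with slide as a block, and animals with low Thy1 by 8 of 8 without them. More microglia under the oligonucleotide is argued against by 0 of 4 genes changing with genotype in the cortex in that direction. A sequence-dependent effect of each oligonucleotide stays open as a candidate explanation, and was not tested because the sequences were not used here.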

How the results depend on the processing

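Leaving out the animals with low Thy1, alone or with slide as a block, and the choroid plexus covariate were chosen only after the data had been seen. No count, Cd33 value or median of the genotype genes was reversed under any alternative run, but without these animals medians of lists turned for cortical control ASO. That of the called immediate early list went from 0.254 to -0.0428, and those of the plaque-associated and the ITAM and ITIM lists, called only then, from -0.0283 to 0.0959 and from -0.0165 to 0.128. Without a filter, with a stricter filter, with normalization within the tissue, with surgery session or replicate number as a block, with the mean of the probes of a gene and without animals collected on another day, all results run kept their direction and side of the threshold, and counts stayed within 1.5 times. The mean of probes was not run for Cd33, which has 1 probe.

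With median centring the hippocampus gave 262 probes for CD33 ASO against control ASO and 456 for CD33 ASO against PBS, the cortex 57 for control ASO and 121 for CD33 ASO against PBS, and the tissue difference 13 for genotype and 0 for CD33 ASO. Median centring also gave 82.1% of the called probes as higher for hippocampal control ASO (50.4% otherwise), while 0 called lists and 0 named called genes changed direction under 4 scalings. With slide as a block Cd33 for genotype in the hippocampus was 0.442 and passed, and counts were 113 for CD33 ASO and 121 for control ASO in the hippocampus and 11 and 0 for the tissue differences. With only the groups compared in the model, that Cd33 value was 0.397 and passed, and counts were 271 for hippocampal CD33 ASO, 83 for cortical control ASO and 104 for cortical CD33 ASO against PBS. With array weights Cd33 passed in the hippocampus for genotype (0.393) and control ASO (0.294), and counts were 216 and 2600. Without background correction, and so without the offset, Cd33 no longer passed in the cortex for genotype (1.08), CD33 ASO (-3.64) and CD33 ASO against PBS (-3.42). The tissue difference for genotype was then 31 probes. That difference was 30 with the authors' table and 19 without animal as a block. With an estimated correlation 8, 1, 0 and 7 lists passed in the hippocampus for genotype, CD33 ASO, control ASO and CD33 ASO against PBS, and 9, 0, 0 and 3 in the cortex.

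Without the animals with low Thy1 Cd33 passed for hippocampal genotype (0.397), 221 and 28 probes were called for CD33 ASO in hippocampus and cortex, 11 lists for cortical control ASO, and 172 probes for the tissue difference of genotype. With slide as a block as well, the Cd33 value was 0.428 and passed, and counts were 92 and 80 for hippocampal CD33 ASO and control ASO, 1057 for cortical genotype, 11 lists for cortical control ASO and 652 probes for cortical CD33 ASO against PBS. With the choroid plexus covariate hippocampal control ASO gave 1029. Except for settings with fewer arrays, the cause was not tested.

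Leaving out 1 array in turn gave hippocampal ranges of 102 to 147 probes and 0.348 to 0.479 for Cd33 for genotype, 326 to 776 and -1.75 to -1.64 for CD33 ASO, 1129 to 2100 and 0.203 to 0.335 for control ASO, and 577 to 797 and -1.5 to -1.37 for CD33 ASO against PBS. In the cortex the ranges were 468 to 679 and 0.804 to 0.898, 38 to 58 and -1.36 to -1.15, 91 to 172 and 0.134 to 0.229, and 140 to 250 and -1.17 to -0.955. Hippocampal Cd33 passed without PBS replicate 4 for genotype (0.479) and without control ASO replicate 6 or PBS replicate 1 for control ASO. Counts moved by over 1.5 times without CD33 ASO replicates 4, 6 and 9 (326, 329 and 327) for hippocampal CD33 ASO, PBS replicates 7 and 8 (1129 and 1131) for control ASO and CD33 ASO replicate 1 (140) for cortical CD33 ASO against PBS. Signal close to background limits Cd33 after CD33 ASO, where 2 of 9 hippocampal arrays detected it.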

Other observations

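The tests of regrouped arrays in this part were chosen before the results were seen, and none was added after.

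For each comparison the arrays were regrouped at random into 100 splits of the same sizes, the real one included, and the number of splits with as many called probes was counted. In the hippocampus it was 1 for genotype (real value 142, highest other 16), 1 for CD33 ASO against control ASO (527, highest other 429), 1 for control ASO against PBS (1698, highest other 125) and 1 for CD33 ASO against PBS (740, highest other 181). In the cortex it was 1 for genotype (609, highest other 2), 1 for CD33 ASO against control ASO (47, highest other 27), 1 for control ASO against PBS (135, highest other 25) and 1 for CD33 ASO against PBS (217, highest other 30). The real split alone reached each of these 8 counts, which is the smallest result that 100 splits can give. This argues against chance for each count taken alone, but the tests were not adjusted for their number. For hippocampal CD33 ASO against control ASO the margin was small. There another split gave 429, and the real count fell to 326 without CD33 ASO replicate 4. The splits moved arrays freely between slides, so they do not exclude a part of slide in the counts, which with slide as a block were 113 for hippocampal CD33 ASO against control ASO and 121 for control ASO against PBS.

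For hippocampal genotype 4 of 100 splits gave as many called gene lists (real value 13, highest other 13), under the limit set beforehand. Other splits reached the real value, and the counts of lists were not adjusted for their number, so chance is not excluded. Nor can chance be excluded for the other 7 counts of lists with the preset correlation. In the hippocampus as many lists were called in 51 splits for CD33 ASO against control ASO (real value 8, highest other 18), 15 for control ASO against PBS (10, highest other 14) and 15 for CD33 ASO against PBS (13, highest other 18). In the cortex they were called in 6 splits for genotype (14, highest other 17), 48 for CD33 ASO against control ASO (9, highest other 17), 43 for control ASO against PBS (6, highest other 14) and 29 for CD33 ASO against PBS (10, highest other 15).

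The median of the genotype-raised genes under CD33 ASO was as large in 9 of 100 splits in the hippocampus (real value 0.206, highest other 0.294) and in 44 in the cortex (0.0897, highest other 0.272), so chance cannot be excluded for either.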
